A study of Mus musculus with 6 samples.

How the data were processed

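Gene expression was measured by RNA sequencing in 6 libraries, 3 of mouse trophoblast stem cells (mTSC) and 3 of trophoblast giant cells (TGC) taken after 7 days of differentiation. The mTSC medium held 25 ng/ml FGF4, heparin and fibroblast-conditioned medium, and the differentiation medium was the same without FGF4 and heparin. The study's descriptions name different RNA extraction methods, TRIzol in one place and a mirVana kit in another. Libraries were made with a NEBNext Ultra RNA kit and sequenced on an Illumina instrument, and neither the strand nor a selection of polyadenylated RNA is stated.

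Per the labels, the authors processed the reads with HISAT2, Cufflinks and HTSeq on the mouse build mm10, with no versions or settings given. The authors gave FPKM values, sequenced fragments scaled to gene length and library size, for 28549 genes, each above 0 in at least 1 library. The columns of the table of all samples were identical to the values of the single samples. The test planned first needed gene counts, and since the values are FPKM the test foreseen for FPKM was used. Gene IDs were matched to the GENCODE M21 annotation of the same build (28511 of 28549 IDs, 27811 with the same symbol). Before that, 1 ID that had lost a zero was restored from its position in the table of all samples. Where a symbol belonged to several IDs, the ID with the same symbol in that annotation kept it, and among several such IDs the one with the higher mean FPKM. Coordinates and exon lengths are from that annotation.

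Depth was checked from the steps between low FPKM values. Multiplied by exon length and a single factor per library, 97.6 to 98.1% of the values worth 0.5 to 20 reads lay within 0.1 of a whole number, with factors of 15570000 to 18600000 reads. Reads recovered this way were used in 1 alternative only. Values that differ by a few reads are not separated at this depth, and reads of close paralogs, such as the prolactin family and Hspa1a with Hspa1b, may have been assigned to either copy.

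Genes with an FPKM of at least 1 in at least 3 libraries were tested (12246 genes). A linear model with group as its only term was fitted to log2(FPKM + 1) in limma 3.58.1 (eBayes with trend), R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Replicate numbers were not used as pairs. Fold changes are TGC less mTSC on that log2 scale, with the standard error of the moderated fit. The 35 gene lists were tested with camera at a preset correlation of 0.01, with adjustment over all lists, and beside it with a correlation estimated from the libraries and with fry. They were written from textbook knowledge before the data were examined. They cover stem cell factors, FGF and ERK response, giant cell markers, prolactins, cathepsins, pregnancy-specific glycoproteins, 2 other trophoblast lineage lists, cell cycle, p53, adhesion, invasion, steroids, cholesterol, vascular factors, imprinting, X-inactivation, DNA methylation, secretion, lysosome, metabolism, ribosome biogenesis, interferon, cytoskeleton, transport, mitochondria and 5 other cell types. Symbol families and chromosomes were tested for enrichment of genes changed at least 2-fold with Fisher's exact test against all tested genes.

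Genes named in the text follow a rule also set before the data were examined. It takes the 8 largest rises and the 8 largest falls among genes past the threshold with at least 10 FPKM in the higher group, no overlap between groups and a gene name. It adds 12 marker genes whatever their result, and from each list the 3 largest changes and the largest of the less frequent direction. Genes under the filter were named with their values where a list's abundant or defining members were not tested. Lists for heat shock, immediate early, short non-coding RNA and histone genes were added after the results were seen.

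The test was checked on simulated data built on the spread of these libraries. Of the genes changed 2-fold 75 of 99 were called, of those changed 4-fold 95 of 100, and 7 of 11573 unchanged genes were called. Few genes were changed in the simulation, while 72% passed the threshold in the data. As the adjustment depends on that share, these rates do not carry over to the real comparison. A planted list of 30 genes was called by camera with the preset and with the estimated correlation. With the preset correlation camera called 0 of 34 other lists. Simulated genes varied independently and the other lists were random, so the 0 does not show how the preset handles correlated members. In the real lists the estimated correlation reached 0.724, and splits of the libraries that mixed the cell types called 9 to 15 lists. These splits kept part of the difference between the cell types, so their lists do not measure false calls.

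The alternatives were another pseudocount (0.1), no filter, a threshold of 0.01, limma's treat against a 2-fold change, replicate number as a block and leaving out each library. Added after the data were seen were a filter at 5 FPKM, median-of-ratios scaling, scaling to the same FPKM total with and without abundant and placental families, quantile normalization, removal of GC content and length trends with and without the replicate block, and limma-voom on recovered reads. Pictures were drawn with matplotlib 3.10.9 under Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1).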

Results

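The data were RNA sequencing values from mouse trophoblast stem cells (mTSC), the proliferating precursors of the placental trophoblast, and from trophoblast giant cells (TGC), the large polyploid cells of the outer placenta. The mTSC were grown with fibroblast growth factor 4 (FGF4), heparin and medium conditioned by mouse embryonic fibroblasts, and the TGC were taken after 7 days of differentiation, in medium without FGF4 and heparin. Each group had 3 libraries. The values, for 28549 genes, were FPKM, which count sequenced fragments scaled to gene length and library size. The steps between low FPKM values put the denominators at 15570000 to 18600000 reads, so that 1 read on 1 kb of exon was worth 0.0538 to 0.0642 FPKM. An FPKM of at least 1 was reached by 11770 ± 83.5 genes per mTSC library and 11751 ± 123 per TGC library (SD, n = 3). On log2(FPKM + 1) across the 12246 tested genes, which are not independent replicates, pairs of libraries correlated at r = 0.990 to 0.992 within mTSC, 0.983 to 0.988 within TGC and 0.814 to 0.846 between the groups. Across all 28549 genes the between-group r was 0.923 to 0.938.

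The comparison of TGC with mTSC addresses which genes change as the stem cells become giant cells. The stem cell transcription factor gene Sox2 fell from 46.6 ± 1.70 to 0.0833 ± 0.144 FPKM (mean ± SD, n = 3 libraries, as in all values that follow), while the placental lactogen gene Prl3b1 rose from 10.8 ± 3.08 to 1384 ± 330 FPKM. Every tested gene of the placental prolactin family rose and every one of the 35 tested mitosis genes fell. In the steroid hormone list 9 of 14 tested genes rose, and in the hypoxia and glycolysis list 23 of 26 fell (adjusted p = 0.267 for both with an estimated correlation). Of 12246 tested genes, 8820 (72%) changed at a Benjamini-Hochberg threshold of 0.05 in limma, 4250 higher and 4570 lower in TGC. With each library scaled to the same FPKM total, the split was 3062 higher and 5749 lower, as the median log2 change of all genes moved from -0.02 to -0.25. The change was at least 2-fold in 3168 genes, 1412 higher and 1756 lower. The 3 values of one group lay outside those of the other in 9270 genes (75.7%, against 10% by chance). The spread behind these tests is that between libraries, and whether the 3 libraries of a group came from separate cultures is not stated. With fold changes taken on log2(FPKM + 1), changes of genes near or below 1 FPKM are understated.

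Of 35 gene lists fixed before the data were examined, 20 changed as sets by camera with a preset correlation between genes, and none did with the correlation estimated from the 6 libraries, where 5 had an unadjusted p under 0.05. A higher correlation does not account for this in every list, as the estimate for stem cell factors was 0.002, below the preset 0.01. Both adjusted p-values are given for each list, and ranges for camera cover its alternatives with the preset correlation. Some lists share genes, so they are not independent of each other. The numbers of list members that rose and fell were the same adjusted over the list alone as over all genes in 34 lists, and the other, ribosome biogenesis, had 20 in place of 19 falling.

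Sox2 had the largest fall of all genes covered by the rule for named genes, with a log2 change of -5.47 (SE 0.11, adjusted p = 7.9e-09). The TGC mean of Sox2 rests on replicate 1, with 0.250 FPKM, and the other libraries were listed at 0. It is a gene of the stem cell factor list and lies on chromosome 3 at 34650405 to 34652461 (mm10). In that list 20 of 24 tested members fell and 3 rose, with a median log2 change of -2.04 (camera adjusted p = 6.16e-06; adjusted p = 0.205 with an estimated correlation). Among the transcription factors that maintain the stem state, Cdx2 fell from 21.6 ± 1.78 to 2.32 ± 0.551 FPKM (adjusted p = 2.0e-07) and Eomes from 15.2 ± 1.41 to 1.06 ± 0.0957 (adjusted p = 4.0e-08). Esrrb fell from 28.5 ± 1.65 to 2.82 ± 0.803 FPKM and Elf5 from 11.5 ± 0.544 to 1.98 ± 0.365. The RNA-binding protein gene Lin28a fell from 47.2 ± 1.10 to 0.917 ± 0.294 FPKM. Nr0b1, which encodes an orphan nuclear receptor, had 21.3 ± 0.259 FPKM in mTSC and was listed at 0 in all 3 TGC libraries. The homeobox gene Rhox9, of an X-linked family of similar genes, rose from 125 ± 14.5 to 618 ± 39.5 FPKM (log2 change 2.30, SE 0.11, adjusted p = 2.0e-07).

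**Figure D1:**
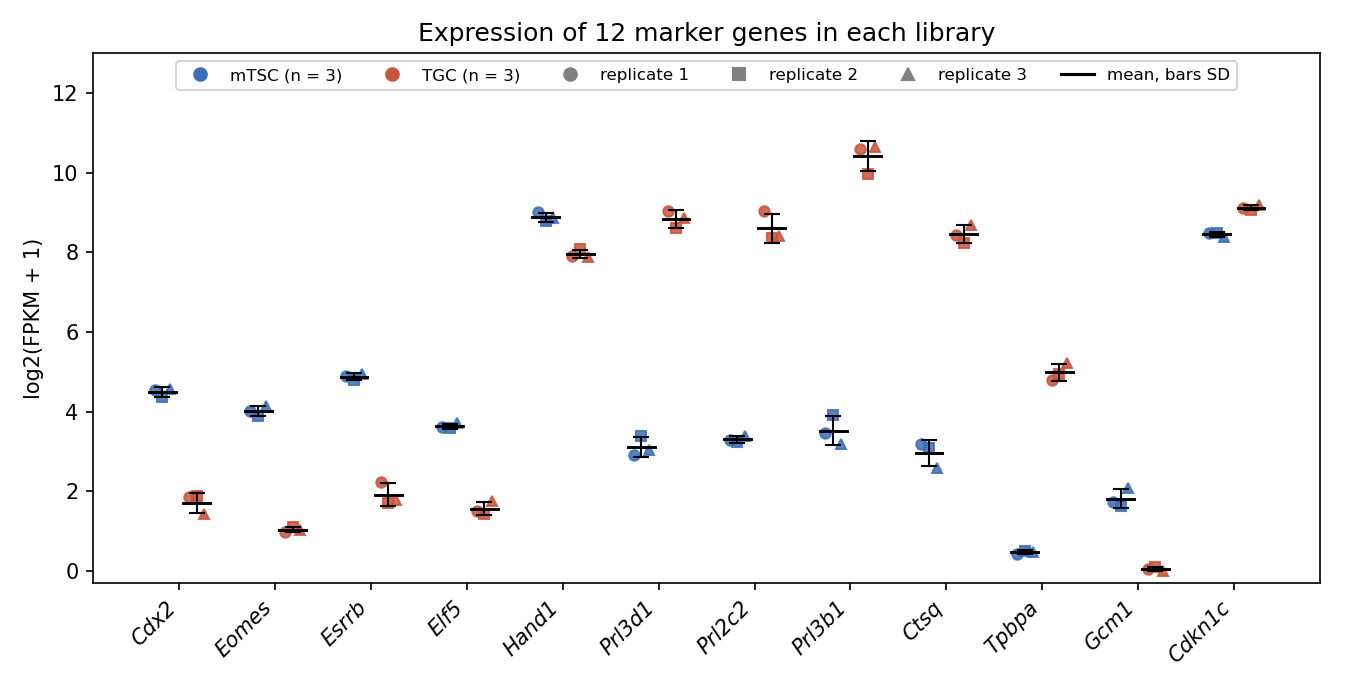
Expression of 12 marker genes chosen before the data were examined, as log2(FPKM + 1) on the vertical axis, with 1 point per library (3 mTSC in blue, 3 TGC in red), a line at the mean and bars of 1 SD. Prl3b1 averages 10.8 FPKM in mTSC and 1384 in TGC, Cdx2 averages 21.6 and 2.32, and Hand1 averages 471 and 248.

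Genes that respond to FGF and ERK signalling fell in 15 of 21 tested cases and rose in 5, with a median log2 change of -1.10 (camera adjusted p = 0.00838; adjusted p = 0.364 with an estimated correlation). That call ended when only genes with at least 5 FPKM were tested (adjusted p = 0.0661; 0.000595 to 0.0661 over all camera alternatives with a preset correlation, and 0.000119 in fry). The feedback inhibitor genes Spred1 and Spry2 fell from 7.11 ± 0.610 to 0.0624 ± 0.0739 FPKM and from 11.3 ± 0.455 to 1.09 ± 0.122, with 0.144 for Spred1 in TGC replicate 2 and less in the others. The ETS factor gene Etv4 fell from 16.8 ± 0.813 to 2.71 ± 0.263 FPKM. Fosl1, a subunit of the AP-1 transcription factor, rose from 2.79 ± 0.308 to 11.4 ± 1.72 FPKM (log2 change 1.70, SE 0.12, adjusted p = 2.1e-06).

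Of 25 placental prolactin family genes with values 18 were tested, and all 18 rose, with a median log2 change of 4.77 (camera adjusted p = 6.76e-11, adjusted p = 0.253 with an estimated correlation). A gene could pass the filter by its TGC values alone, as Prl7d1 did, which averaged 0.960 FPKM in mTSC. The share of the family in the FPKM total went from 0.042% ± 0.003 to 1.538% ± 0.243. Prl3b1, the gene for placental lactogen II, lies on chromosome 13 at 27241847 to 27249683 and had a log2 change of 6.88 (SE 0.22, adjusted p = 2.3e-08). Prl3d1, the gene for placental lactogen I, at 27094190 to 27100258 on the same chromosome, rose from 7.77 ± 1.56 to 458 ± 68.6 FPKM. The proliferin gene Prl2c2 rose from 8.89 ± 0.580 to 397 ± 107 FPKM. Values of Prl3d1 and Prl2c2 cannot be fully separated from those of their close paralogs. Prl7d1 rose from 0.960 ± 0.372 to 176 ± 28.7 FPKM and Prl7a1 from 6.59 ± 0.416 to 334 ± 78.0. Of 7 placental cathepsins with values 4 were tested, and these rose too (median log2 change 4.98, camera adjusted p = 0.00105, adjusted p = 0.269 with an estimated correlation). Of these proteases, Ctsj rose from 179 ± 26.9 to 7324 ± 1016 FPKM, Ctsr from 12.7 ± 2.41 to 331 ± 49.0, and Ctsq from 6.90 ± 1.63 to 351 ± 55.7. The cathepsin list made up 0.066% ± 0.009 of the FPKM total in mTSC and 2.198% ± 0.266 in TGC. Among 21 pregnancy-specific glycoprotein and related Ceacam genes with values, 5 were tested and 4 of these rose (median log2 change 2.35, camera adjusted p = 0.0105, adjusted p = 0.312 with an estimated correlation). Of these, Psg22 passed the filter by its TGC values. Psg29 rose from 1.01 ± 0.224 to 10.1 ± 1.61 FPKM, Psg22 from 0.833 ± 0.051 to 8.32 ± 0.478, and Ceacam9 from 3.74 ± 0.619 to 28.2 ± 0.275.

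The wider list of giant cell markers went mostly up, with 14 of 22 tested members higher and 5 lower (median log2 change 0.97, camera adjusted p = 0.00189; adjusted p = 0.267 with an estimated correlation). Its largest changes, in Prl3b1, Prl3d1 and Ctsq, are also counted in the prolactin or cathepsin list, so it is not separate from those lists. Hand1, a transcription factor gene needed for giant cell formation, was among those that fell, from 471 ± 37.5 to 248 ± 17.9 FPKM (log2 change -0.92, SE 0.10, adjusted p = 3.7e-05). Cdkn1c, an inhibitor of cyclin-dependent kinases, rose from 348 ± 14.3 to 555 ± 26.6 FPKM (log2 change 0.67, adjusted p = 0.00018). After quantile normalization its log2 change was 0.23 and no longer past the threshold (adjusted p = 0.056).

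Markers of the other trophoblast lineages mostly fell. In the spongiotrophoblast and glycogen cell list 12 of 15 tested members fell and 3 rose (median log2 change -0.83, camera adjusted p = 0.00765; adjusted p = 0.364 with an estimated correlation). The transcription factor gene Ascl2 fell from 37.5 ± 2.60 to 1.99 ± 0.472 FPKM and the connexin gene Gjb3 from 286 ± 12.5 to 31.3 ± 4.74. Tpbpa, a marker of spongiotrophoblast and its precursors, rose from 0.391 ± 0.0414 to 30.9 ± 4.73 FPKM (log2 change 4.51, SE 0.12, adjusted p = 1.4e-08). In the syncytiotrophoblast and labyrinth list 13 of 19 tested members fell and 4 rose (median log2 change -0.89, camera adjusted p = 0.012; adjusted p = 0.269 with an estimated correlation). Gcm1, a regulator of syncytiotrophoblast formation, fell from 2.56 ± 0.624 to 0.0366 ± 0.0397 FPKM, with 0.0788 in TGC replicate 2 and less in the others. The lactate transporter gene Slc16a3 fell from 201 ± 17.6 to 24.0 ± 2.58 FPKM and the transcription factor gene Cebpa from 9.69 ± 0.574 to 1.04 ± 0.223. Ovol1, another transcription factor gene of this list, rose from 1.17 ± 0.139 to 2.64 ± 0.598 FPKM.

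All 35 tested mitosis genes fell, with a median log2 change of -2.40 (camera adjusted p = 1.2e-14; adjusted p = 0.269 with an estimated correlation). Top2a, the topoisomerase gene of dividing cells, on chromosome 11 at 98992943 to 99024189, fell from 83.2 ± 9.91 to 4.75 ± 0.496 FPKM. Cyclin B2 (Ccnb2) fell from 61.3 ± 2.28 to 3.49 ± 0.369 FPKM and Ube2c, which acts in the exit from mitosis, from 38.4 ± 2.80 to 2.19 ± 0.490. DNA replication genes fell in 27 of 34 tested cases and rose in 1, with a smaller median log2 change of -0.88 (camera adjusted p = 6.16e-06; adjusted p = 0.267 with an estimated correlation). Mcm3, of the replicative helicase, fell from 52.2 ± 1.38 to 9.29 ± 1.89 FPKM, the ligase gene Lig1 from 28.6 ± 1.14 to 4.34 ± 0.895, and Uhrf1 from 51.5 ± 1.12 to 4.34 ± 0.291. The origin recognition gene Orc6 rose from 19.9 ± 1.11 to 26.8 ± 1.94 FPKM, a call that ended with libraries scaled to the same FPKM total (log2 change 0.16, adjusted p = 0.171). The mean log2(FPKM + 1) of the mitosis list less that of the replication list was 0.30 ± 0.06 in mTSC and -1.08 ± 0.08 in TGC, a difference of -1.39 (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give). Regulators of the endocycle and G1, the phases relevant to polyploid growth, were not past the threshold as a list, with 5 of 24 tested members higher and 13 lower (camera adjusted p = 0.146; adjusted p = 0.473 with an estimated correlation). The list was past the threshold, lower in TGC, with no filter (adjusted p = 0.00956; 0.00956 to 0.347 in camera) and in fry (0.000679). Within it the cyclin genes Ccnd1 and Ccnd3 fell, from 3.70 ± 0.464 to 0.130 ± 0.0654 and from 37.5 ± 1.68 to 10.3 ± 1.35 FPKM. Fbxo5, an inhibitor of the anaphase-promoting complex, fell from 22.9 ± 1.67 to 6.40 ± 1.36 FPKM, while the kinase inhibitor gene Cdkn2b rose from 5.59 ± 0.524 to 15.2 ± 1.42. Targets of p53 went both ways, 8 of 21 up and 10 down (camera adjusted p = 0.7; adjusted p = 0.892 with an estimated correlation). Sesn1 rose from 9.01 ± 0.246 to 40.5 ± 5.77 FPKM and Gdf15 from 0.616 ± 0.371 to 3.13 ± 0.939, and Zmat3 fell from 17.3 ± 1.21 to 4.67 ± 0.732. The mTSC mean of Gdf15 rests on replicate 2, as the 3 libraries had 0.397, 1.04 and 0.406 FPKM.

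**Figure D2:**
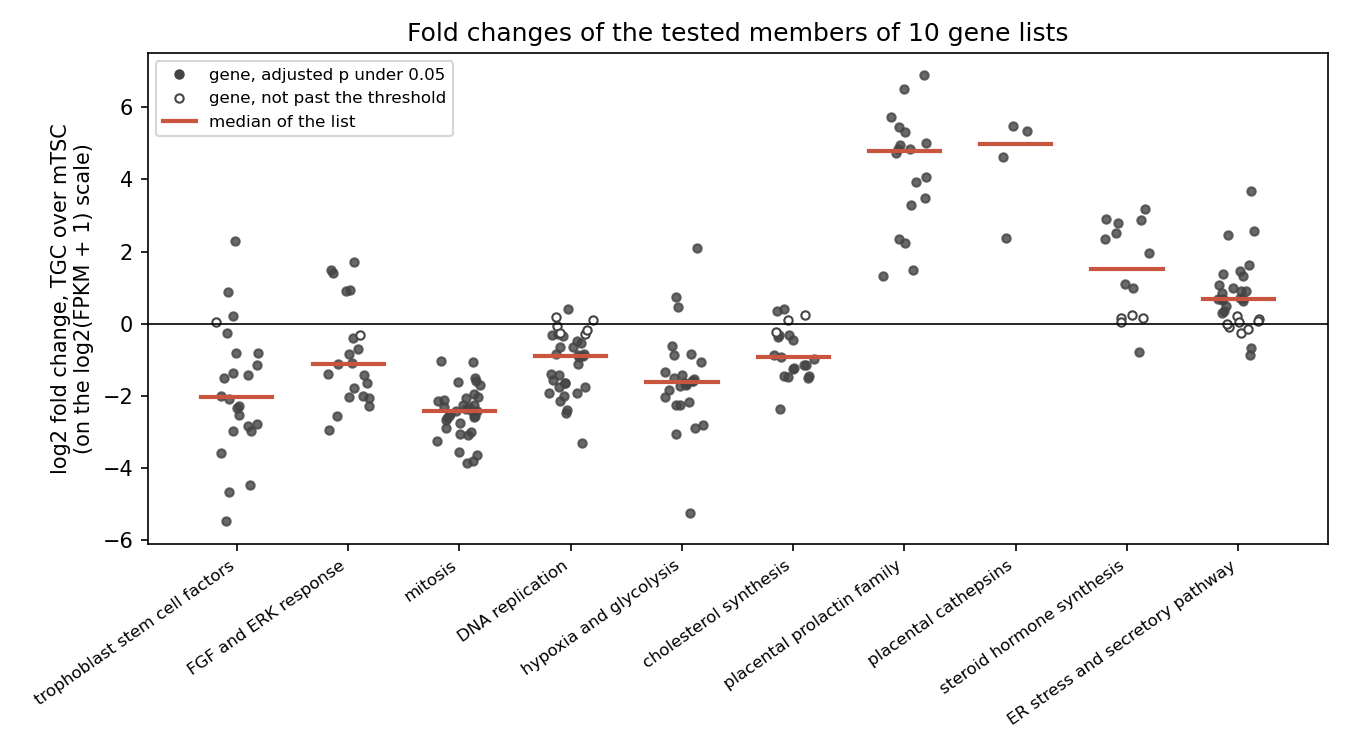
Log2 fold change of TGC over mTSC on the log2(FPKM + 1) scale (vertical axis) for each tested gene of 10 gene lists (horizontal axis), with 1 point per gene, open where it was not past the threshold, and a red line at the median of the list. The 35 mitosis genes all lie below 0 around a median of -2.40 and the 18 prolactin genes all lie above 0 around a median of 4.77.

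Steroid hormone synthesis genes rose in 9 of 14 tested cases and fell in 1, with a median log2 change of 1.52 (camera adjusted p = 0.000444; adjusted p = 0.267 with an estimated correlation). Cyp11a1, which makes pregnenolone from cholesterol, rose from 4.13 ± 0.473 to 45 ± 4.06 FPKM (log2 change 3.17, SE 0.11, adjusted p = 3.3e-08). Star, which carries cholesterol into mitochondria, rose from 1.77 ± 0.197 to 19.8 ± 1.14 FPKM, and Hsd3b6, of progesterone synthesis, from 0.547 ± 0.125 to 10.4 ± 1.01. Srd5a1, a steroid reductase gene, fell from 5.52 ± 0.052 to 2.88 ± 1.12 FPKM. Cholesterol synthesis genes fell in 16 of 21 tested cases and rose in 2 (median log2 change -0.91, camera adjusted p = 0.00198; adjusted p = 0.267 with an estimated correlation). Dhcr24 fell from 30.2 ± 0.698 to 5.12 ± 1.08 FPKM, the sterol regulator gene Srebf2 from 46.7 ± 2.47 to 16.1 ± 1.47, and Stard4 from 10.6 ± 1.42 to 3.19 ± 0.203. Msmo1 rose from 6.08 ± 0.789 to 8.43 ± 0.207 FPKM, past the threshold as measured but not with libraries scaled to the same FPKM total (adjusted p = 0.189).

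Genes of endoplasmic reticulum stress and the secretory pathway rose in 21 of 31 tested cases and fell in 2, with a median log2 change of 0.68 (camera adjusted p = 0.000282; adjusted p = 0.312 with an estimated correlation). Herpud1, which acts in the degradation of misfolded proteins, rose from 3.57 ± 0.989 to 56.5 ± 2.27 FPKM (log2 change 3.67, SE 0.14, adjusted p = 5.8e-08). The stress-induced genes Ddit3 and Trib3 rose from 21.9 ± 1.83 to 135 ± 12.2 and from 11.2 ± 1.62 to 66.1 ± 4.11 FPKM. The retrieval receptor gene Kdelr3 fell from 9.71 ± 1.52 to 4.87 ± 0.981 FPKM. Lysosome and autophagy genes rose in 15 of 31 tested cases and fell in 6, near the threshold (median log2 change 0.18, camera adjusted p = 0.0493; adjusted p = 0.664 with an estimated correlation). That call ended in 11 of 18 other settings, with adjusted p from 0.00557 to 0.177 in camera and 0.00643 in fry, and the median turned to -0.03 with libraries scaled to the same FPKM total. It ended without mTSC replicate 2 (adjusted p = 0.0549), mTSC replicate 3 (0.0646), TGC replicate 2 (0.0739) or TGC replicate 3 (0.0841). Ctsl rose from 34.4 ± 3.70 to 115 ± 3.64 FPKM, the sterol carrier gene Npc2 from 29.7 ± 1.68 to 95.9 ± 7.39, and the proton pump gene Atp6v0d1 from 95.6 ± 6.72 to 216 ± 17.6. Tfeb, a regulator of lysosome genes, fell from 25.5 ± 1.87 to 13.1 ± 1.24 FPKM.

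Hypoxia and glycolysis genes fell in 23 of 26 tested cases and rose in 3, with a median log2 change of -1.60 (camera adjusted p = 1.71e-06; adjusted p = 0.267 with an estimated correlation). The glucose transporter gene Slc2a3 fell from 138 ± 5.35 to 2.74 ± 0.705 FPKM (log2 change -5.23, SE 0.13, adjusted p = 1.4e-08). Hk2, of the first step of glycolysis, fell from 31.2 ± 0.386 to 2.95 ± 0.521 FPKM and Pgam1 from 416 ± 19.3 to 55.7 ± 3.52. Epas1, a hypoxia-inducible factor gene, rose from 3.79 ± 0.354 to 19.6 ± 0.410 FPKM. Nuclear genes of oxidative phosphorylation went both ways, 9 of 23 up and 8 down, with a median log2 change of 0.21 and a mean of -0.03 (camera adjusted p = 0.813; adjusted p = 0.92 with an estimated correlation). Of these, Uqcrfs1 fell from 111 ± 5.34 to 41.2 ± 2.39 FPKM, Atp5a1 from 313 ± 16.8 to 163 ± 23.2, and Sdha from 61.7 ± 4.69 to 31.9 ± 4.40. Mitochondrially encoded genes rose in 7 of 13 tested cases and fell in 1, not past the threshold as a list (camera adjusted p = 0.111; adjusted p = 0.664 with an estimated correlation). The list was past it without TGC replicate 3 (adjusted p = 0.0285) and with libraries scaled to the same FPKM total (0.0479), over a range of 0.0285 to 0.565 in camera and with 0.12 in fry. Of its abundant members, mt-Co1 rose from 6114 ± 944 to 11453 ± 1806 FPKM, and mt-Nd1 had 1609 ± 289 and 1401 ± 442, not past the threshold. Values were lower for mt-Co3, at 9.0 ± 2.12 and 36.6 ± 13.3 FPKM, for mt-Co2, at 25.2 ± 4.37 and 78.7 ± 24.3, and for mt-Atp6, at 14.9 ± 1.90 and 73.0 ± 56.4. Whether these low values are RNA levels or come from how reads were assigned was not tested. The mt-Atp6 mean in TGC rests on replicate 1, as the 3 libraries had 138, 40.3 and 40.7 FPKM. The strand was not stated, so mt-Nd6, with 223 ± 29.2 and 130 ± 8.49 FPKM, cannot be separated from RNA of the opposite strand. Ribosome biogenesis genes fell in 19 of 23 tested cases and rose in 1 (median log2 change -0.69, camera adjusted p = 0.000444; adjusted p = 0.269 with an estimated correlation). Polr1b, of RNA polymerase I, fell from 15.9 ± 0.614 to 2.12 ± 0.146 FPKM, Mybbp1a from 132 ± 7.89 to 28.2 ± 3.56, and Dkc1 from 6.39 ± 0.565 to 1.08 ± 0.125. Bop1 rose from 24.4 ± 2.47 to 34.2 ± 1.18 FPKM, a call that ended with libraries scaled to the same FPKM total (adjusted p = 0.0777). Solute and nutrient transport genes were not past the threshold as a list, 5 of 21 up and 12 down (camera adjusted p = 0.146; adjusted p = 0.664 with an estimated correlation). That list was past it, lower in TGC, with no filter (adjusted p = 0.0249; 0.0249 to 0.311 in camera) and in fry (0.00544). The lipid transporter gene Mfsd2a rose from 5.93 ± 0.576 to 35.1 ± 1.92 FPKM and the glutamine transporter gene Slc1a5 fell from 7.20 ± 0.512 to 0.789 ± 0.118.

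DNA methylation genes fell in 9 of 11 tested cases and rose in 0, with a median log2 change of -1.02 (camera adjusted p = 0.00189; adjusted p = 0.269 with an estimated correlation). The methyltransferase gene Dnmt3b fell from 33.5 ± 1.72 to 1.17 ± 0.406 FPKM (log2 change -4.01, SE 0.14, adjusted p = 4.0e-08) and Dnmt1 from 70.2 ± 0.507 to 12 ± 1.87. X-inactivation and polycomb genes fell in 7 of 11 tested cases and rose in 1, not past the threshold as a list (camera adjusted p = 0.0649; adjusted p = 0.554 with an estimated correlation). Without mTSC replicate 1 the list was past it (adjusted p = 0.0468; 0.00407 to 0.104 over the preset camera alternatives, and 0.000602 in fry). Xist, the RNA that coats the inactive X chromosome, fell from 80.4 ± 9.99 to 18.5 ± 3.59 FPKM, and the polycomb gene Cbx2 from 28.0 ± 1.58 to 7.77 ± 0.147. Bmi1, also of polycomb, rose from 4.10 ± 0.670 to 14.7 ± 5.45 FPKM. Imprinted genes fell in 21 of 31 tested cases and rose in 7 (median log2 change -0.64, camera adjusted p = 0.0174; adjusted p = 0.364 with an estimated correlation). Their call ended when only genes with at least 5 FPKM were tested (adjusted p = 0.0961) and with libraries scaled to the same FPKM total (0.0509), over a range of 0.00211 to 0.0961 in camera and with 0.000224 in fry. Mest fell from 11.7 ± 2.21 to 0.506 ± 0.169 FPKM, Cd81 from 22.2 ± 0.599 to 1.86 ± 0.666, and the non-coding RNA H19 rose from 11.8 ± 2.21 to 42.4 ± 5.11.

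Epithelial adhesion genes went both ways, 9 of 25 up and 13 down (camera adjusted p = 0.331; adjusted p = 0.554 with an estimated correlation). E-cadherin (Cdh1) fell from 176 ± 14.7 to 23.8 ± 4.6 FPKM, and the claudin genes Cldn6 and Cldn3 fell from 52.7 ± 1.71 to 2.45 ± 0.835 and from 106 ± 16.5 to 15.6 ± 0.709. Keratin 18 (Krt18) rose from 2326 ± 144 to 6059 ± 154 FPKM. Of mesenchymal transition genes 5 of 8 rose and 3 fell (camera adjusted p = 0.452; adjusted p = 0.664 with an estimated correlation). Fibronectin (Fn1) rose from 51.6 ± 4.45 to 172 ± 19.8 FPKM and Sparc from 154 ± 5.43 to 287 ± 32.8, and Loxl2 fell from 3.50 ± 0.475 to 0.786 ± 0.292. Matrix protease and invasion genes rose in 5 of 18 tested cases and fell in 7 (camera adjusted p = 0.505; adjusted p = 0.841 with an estimated correlation). The protease inhibitor gene Serpine1 rose from 150 ± 7.18 to 545 ± 56.6 FPKM, and the integrin genes Itgav and Itgb5 fell from 23.1 ± 0.197 to 6.11 ± 0.488 and from 73.9 ± 0.930 to 23.0 ± 1.84. Actin and contractile genes rose in 11 of 22 tested cases and fell in 10, with a median log2 change of 0.03 and a mean of -0.02 (camera adjusted p = 0.843; adjusted p = 0.92 with an estimated correlation). Cyr61 rose from 19.8 ± 3.19 to 136 ± 38.1 FPKM, while filamin A (Flna) fell from 26.3 ± 0.512 to 4.17 ± 1.51 and the myosin gene Myh9 from 112 ± 2.94 to 20.8 ± 2.10. Vascular and vasoactive factors rose in 7 of 18 tested cases and fell in 9 (camera adjusted p = 0.781; adjusted p = 0.831 with an estimated correlation). The anticoagulant gene Tfpi rose from 21.5 ± 1.11 to 228 ± 41.9 FPKM and the protein C receptor gene Procr from 21.8 ± 1.02 to 97.6 ± 6.30, and endoglin (Eng) fell from 12.6 ± 1.53 to 0.621 ± 0.237. Interferon response genes fell in 12 of 18 tested cases and rose in 3, not past the threshold as a list (camera adjusted p = 0.0649; adjusted p = 0.473 with an estimated correlation). It was past the threshold without mTSC replicate 3 (adjusted p = 0.0475) or TGC replicate 3 (0.0339), over a range of 0.00503 to 0.317 in camera and with 0.000962 in fry. Isg15 fell from 92.9 ± 19.8 to 24.5 ± 1.48 FPKM, Ifit1 from 4.38 ± 0.237 to 0.770 ± 0.0469, and Ifi27l2a from 5.0 ± 0.310 to 0.887 ± 0.223, while Irf9 rose from 9.57 ± 0.332 to 27.1 ± 2.43.

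**Figure D3:**
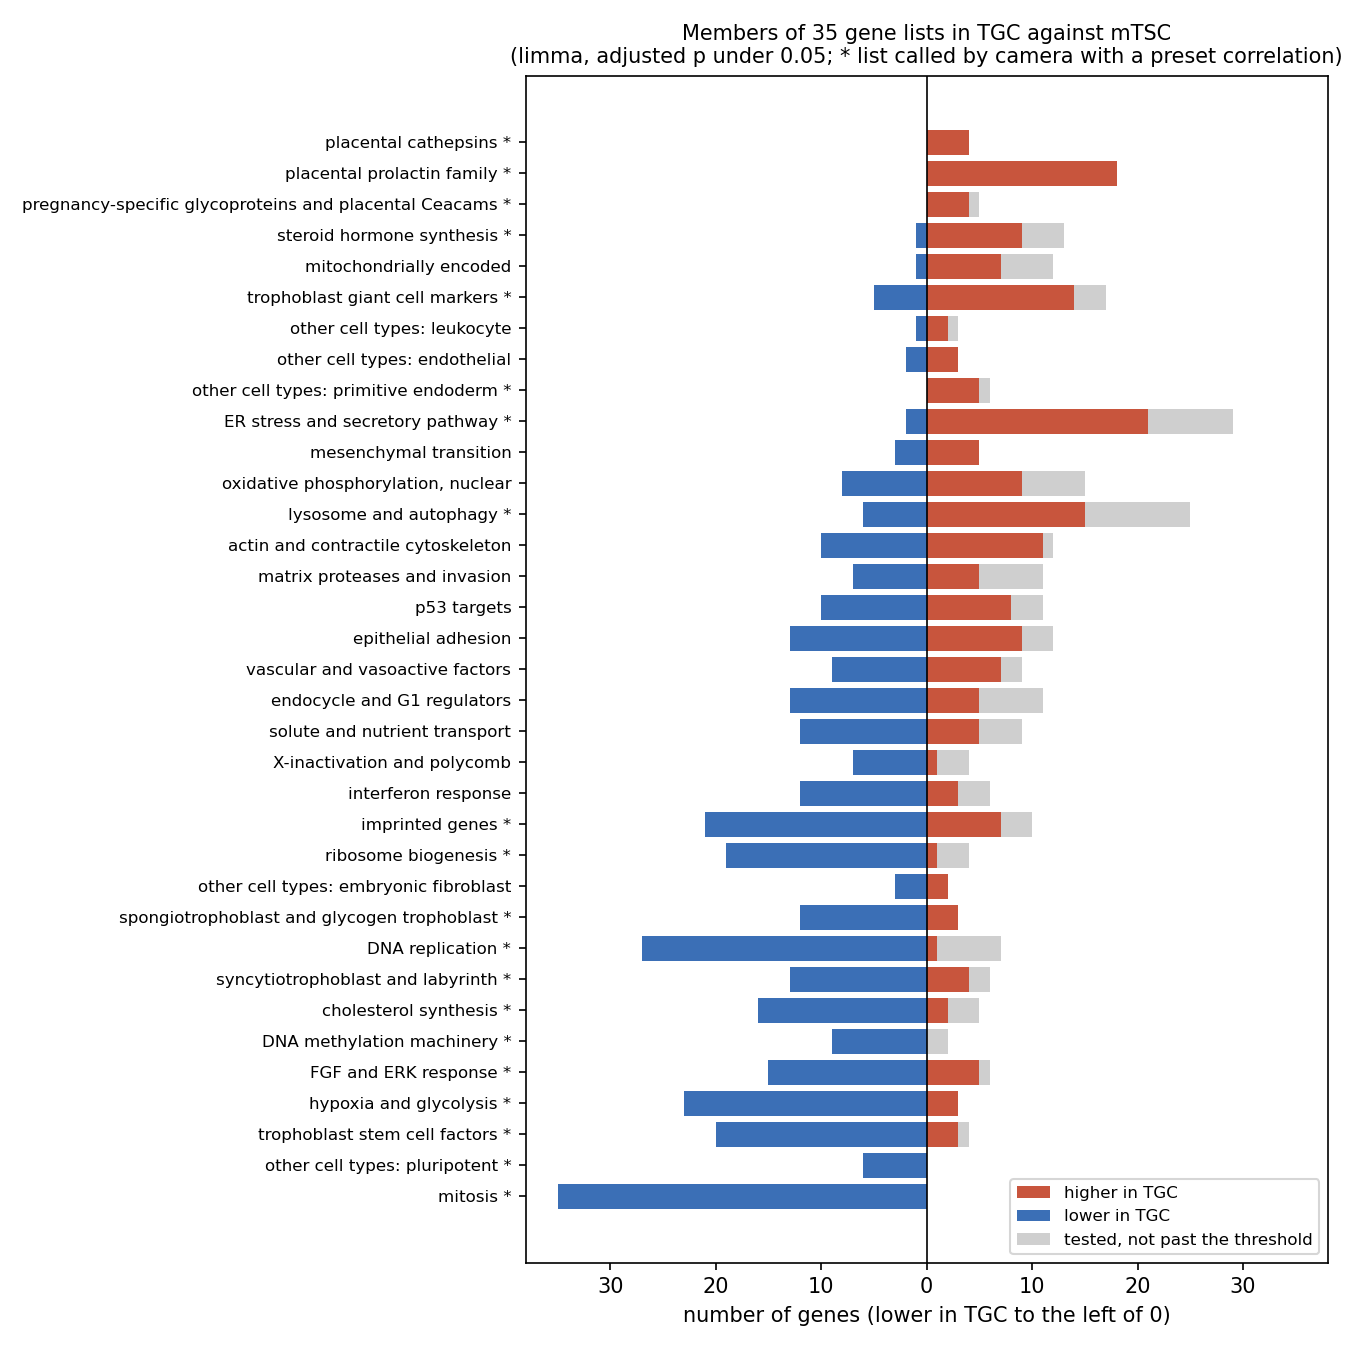
Number of tested genes of each gene list (rows) that were lower in TGC (left of 0), higher in TGC (right of 0) or not past the threshold (grey) in limma with 3 libraries per group, with an asterisk at the 20 lists called by camera with a preset correlation. The mitosis list has 35 genes lower and 0 higher, and the prolactin list 18 higher and 0 lower.

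Markers of cell types that a trophoblast culture or its conditioned medium could carry were measured beside these groups. For the fibroblast, pluripotency and primitive endoderm lists, 1 tested member each is in another list as well. Of 21 embryonic fibroblast markers 5 were tested, 2 higher and 3 lower (camera adjusted p = 0.848; adjusted p = 0.92 with an estimated correlation). The abundant fibroblast collagen gene Col1a1 stayed under the filter at 0.958 ± 0.137 FPKM in mTSC and 0.0661 ± 0.0272 in TGC. Pdgfra rose from 1.19 ± 0.0612 to 5.06 ± 0.507 FPKM and Pdgfrb from 1.22 ± 0.108 to 3.89 ± 0.817, and Col6a1 fell from 2.55 ± 0.307 to 0.641 ± 0.150. All 6 tested pluripotency markers fell (median log2 change -2.30, camera adjusted p = 0.00105; adjusted p = 0.253 with an estimated correlation), among them Klf2 from 25.9 ± 3.82 to 0.942 ± 0.377 FPKM, Utf1 from 99.95 ± 18.4 to 7.16 ± 1.81 and Tbx3 from 7.28 ± 0.567 to 0.654 ± 0.134. Pou5f1, a core pluripotency gene, was at most 0.0239 FPKM in an mTSC library and listed at 0 in the 3 TGC libraries. Of 6 tested primitive endoderm markers 5 rose (median log2 change 0.68, camera adjusted p = 0.0231; adjusted p = 0.269 with an estimated correlation). That call ended with no filter (adjusted p = 0.104), with only genes of at least 5 FPKM (0.0544) and with reads recovered from the FPKM steps (0.0763), over a range of 0.00731 to 0.104 in camera and with 9.77e-05 in fry. The laminin gene Lama1 rose from 1.13 ± 0.0690 to 10.5 ± 1.17 FPKM and the collagen gene Col4a1 from 90.4 ± 4.39 to 166 ± 14.2, while Sox17 was at most 0.159 in a library. Endothelial markers rose in 3 of 5 tested cases and fell in 2 (camera adjusted p = 0.57; adjusted p = 0.664 with an estimated correlation). Cdh5 rose from 20.8 ± 3.21 to 93.7 ± 13.2 FPKM and Esam from 6.95 ± 1.15 to 36.7 ± 4.70, and Robo4 fell from 1.65 ± 0.120 to 0.118 ± 0.0545. Leukocyte markers rose in 2 of 4 tested cases and fell in 1, with a median log2 change of 0.75 and a mean of -0.08 (camera adjusted p = 0.594; adjusted p = 0.664 with an estimated correlation). Csf1r rose from 10.8 ± 1.17 to 36.1 ± 2.76 FPKM and Cd68 from 36.1 ± 3.62 to 105 ± 13.3, and Laptm5 fell from 17.2 ± 1.48 to 0.633 ± 0.221. Ptprc, the leukocyte common antigen gene, was listed at 0 in mTSC and was at most 0.0297 FPKM in a TGC library.

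The largest rises and falls also included genes outside the lists. Rn7sk, a short non-coding RNA that lacks a poly(A) tail, on chromosome 9 at 78175303 to 78175633, went from 0.726 ± 0.784 to 527 ± 187 FPKM (log2 change 8.29, SE 0.31, adjusted p = 5.5e-08). Its mTSC mean rests on replicate 3, as the 3 libraries had 0.371, 0.183 and 1.62 FPKM. The mRNA of replication-dependent histone genes typically lacks a poly(A) tail too, though not for every gene. Of the 55 such genes with values, 47 had a higher mean in TGC and 8 a lower one. Their median log2 change was 0.50 when no filter was applied. The heat shock genes Hspa1b and Hspa1a, near-identical neighbours on chromosome 17, rose from 2.80 ± 0.262 to 650 ± 213 FPKM and from 0.929 ± 0.109 to 256 ± 69.0 (log2 changes 7.36 and 7.02). A list of immediate early genes had a median log2 change of 1.21 and a mean of 0.75. Among the falls, the POU factor gene Pou3f1 went from 59.1 ± 4.52 to 0.479 ± 0.189 FPKM (log2 change -5.35, SE 0.12, adjusted p = 8.7e-09). The signalling genes Wnt6 and Efna3 fell from 35.7 ± 2.10 to 0.521 ± 0.122 and from 23.6 ± 1.4 to 0.376 ± 0.165 FPKM. Chd4, the ATPase gene of a chromatin remodelling complex, fell from 83.2 ± 3.61 to 3.25 ± 0.211 FPKM.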

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

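The filter at 5 FPKM, the scalings, the GC and length corrections and the voom fit were chosen after the data were seen. The alternatives planned for gene counts (other size factors, count tests, count filters) were not run on counts, as the values are FPKM. Nearest to them, median-of-ratios scaling of FPKM gave 8831 changed genes and limma-voom on recovered reads 8756. The number of changed genes stayed within 1.5 times of 8820 in 18 of 19 alternatives (6283 to 10015; higher 3053 to 4917, lower 3230 to 5749), and leaving out 1 library gave 8125 to 8725. It was 1647 against a 2-fold change in limma's treat, by that test's construction. Genes changed at least 2-fold numbered 2295 to 4165 (2-fold higher 943 to 1851, 2-fold lower 1320 to 2453). Libraries with the same replicate number did not deviate together (r = -0.014, -0.008 and -0.176 across genes), and with replicate number as a block 8624 genes and 19 lists changed. The 20 changed lists became 16 to 28 in 18 alternatives, 19 to 21 leaving out 1 library and 28 with fry. They became 0 in camera with an estimated correlation, where 5 lists had an unadjusted p under 0.05. The cause was not tested, but a correlation above the preset 0.01 cannot be it for every list. Estimated correlations were 0.002 for stem cell factors and -0.133 for pluripotency markers, whose adjusted p still went to 0.205 and 0.253. The other called lists had estimates above the preset, up to 0.724 for cathepsins. Of the 20 lists, 16 kept their call in the 18 alternatives other than the estimated correlation. None turned in its test, but the lysosome median went to -0.03 with libraries at the same FPKM total. The calls that ended were those of lysosome, imprinted, FGF and ERK, and primitive endoderm genes. Of 15 lists not called, 9 gained a call in at least 1 alternative, 8 of them in fry, which tests a list alone and not against other genes, and 4 there only: epithelial (0.000254), mesenchymal (0.0147), matrix protease (0.0148) and endothelial genes (0.014). The direction of the test turned in lists not called: vascular factors with libraries at the same FPKM total (adjusted p = 0.929), oxidative phosphorylation there (0.895), after quantile normalization (0.742), after GC and length correction (0.57), with block (0.535) and in fry (0.629), and fibroblast markers at the same FPKM total (0.895), after that correction (0.825), with block (0.905) and in fry (0.629). Actin genes turned after quantile normalization (0.729) and in fry (0.741), and leukocyte markers in fry (0.938); the cause was not tested. With only genes of at least 5 FPKM, no fibroblast marker was left to test. Of 128 named genes 103 kept call and direction in all 19 alternatives, none turned, 25 lost the call against a 2-fold change, and Bop1, Msmo1, Orc6 and Cdkn1c lost it in others. Orc6 also lost it after GC and length correction with block (adjusted p = 0.0516). For a gene with 1 kb of exon, 1 FPKM is 15.57 to 18.6 reads, so changes of a few reads are out of reach.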

Other observations

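The heat shock, immediate early, short non-coding RNA and histone lists, and the tests of the heat shock, short non-coding RNA and mitosis patterns, were chosen after the results were seen, as were the families, chromosomes and genes named here. Of 171 families of genes that share a symbol stem and have at least 8 tested members, 5 held more genes at least 2-fold higher in TGC than the other tested genes did, and 1 held more lower ones. Apart from the prolactins (18 of 18, Fisher's exact adjusted p = 4.04e-15), these included the serpin B protease inhibitors, with 9 of 12 higher (adjusted p = 6.37e-05). Serpinb9d went from 6.89 ± 0.895 to 102 ± 19 FPKM and Serpinb9e from 42.7 ± 2.14 to 279.6 ± 13 (n = 3). Keratins were higher in 6 of 10 cases (adjusted p = 0.0221) and the Dnajb chaperones in 5 of 8 (adjusted p = 0.0478). Serpinb1b and Krt42, at 0.0525 and 0.715 FPKM in mTSC, passed the filter by their TGC values. Histones were higher in 14 of 16 cases, but 13 of the 16 averaged under 1 FPKM in mTSC and passed the filter by their TGC values. Genes with the symbol stem Kif were lower in 15 of 28 cases (adjusted p = 0.000106), all 15 among the 27 that encode kinesins and not Kif1bp, a kinesin-binding protein gene. On the X chromosome 66 genes (16.5% of those tested) were at least 2-fold higher (adjusted p = 0.0242 over chromosomes), with a median log2 change of -0.06 over all its genes. Chromosome 13 had 18.3% of genes higher (Fisher's exact adjusted p = 0.000277), and without its clustered prolactin, cathepsin, serpin B and histone genes 42 of 431 (9.7%, Fisher's exact p = 0.856). In the mitochondrial genome 7 of 15 genes (46.7%) were at least 2-fold higher (Fisher's exact adjusted p = 0.0156), while the list of 13 such genes was not past the threshold in camera (adjusted p = 0.111). Fisher's exact test counts the genes of a family or chromosome as independent, while the estimated correlation in that list was 0.626. TGC replicate 1 had the highest mitochondrial share of FPKM, 6.05% against 4.47 and 4.19%, and without it 6 of the 15 were at least 2-fold higher (Fisher's exact p = 0.00413).

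Heat shock genes were higher in TGC, 24 of 27 of them past the threshold and 2 lower, with a median log2 change of 1.10 (camera adjusted p = 5.53e-07; adjusted p = 0.148 with an estimated correlation). Dnajb1 went from 51.9 ± 4.09 to 551 ± 144 FPKM and Hsph1 from 17.5 ± 1.95 to 235 ± 25.6. A single TGC library as the source is argued against by a median of at least 1.05 without any one of them, and library scaling as the whole cause by a median of at least 0.80 over 4 scalings, 1 of which moved the median of all genes to -0.25. A stress at harvest remains open. Immediate early genes had a median log2 change of 1.21 and a mean of 0.75, and 15 of 23 rose and 4 fell (camera adjusted p = 0.0042, adjusted p = 0.435 with an estimated correlation). Jun went from 20.3 ± 0.677 to 194.9 ± 42.4 FPKM, and Klf2 was lower. A lasting difference between the cell types also stays open and was not tested.

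Short non-coding RNA had a higher mean in TGC in all 7 listed genes with values, 5 of them listed at 0 in mTSC, and the 3 tested ones (Rn7sk, Rprl3 at 8.20 ± 1.93 FPKM and Vaultrc5 at 3.0 ± 0.882 in TGC) passed the filter by their TGC values. More RNA without a poly(A) tail in the TGC libraries stays open: 15 of 16 tested histones rose (median log2 change 1.77), but with no filter all 55 had a median of 0.50 (0.31 to 0.64 by TGC library). Of the 3 with at least 1 FPKM in mTSC, Hist1h2bc went from 9.46 ± 0.310 to 75.0 ± 16.8 FPKM, Hist1h4i rose less and Hist1h1c had 14.6 ± 1.81 and 12.3 ± 2.12. The summed FPKM of the 55 histones went from 39.8 ± 2.31 to 166 ± 34.4, and without Hist1h2bc from 30.4 ± 2.52 to 90.7 ± 19.7. Poly(A) tails were not measured, and not every histone mRNA need lack one, so the histones are an imperfect gauge. Better recovery of short transcripts stays open too: 36 protein-coding genes with under 500 bp of exon lay 0.75 above longer ones, but 0.38 among genes with at least 1 FPKM in mTSC. A difference in these RNAs between the cell types stays open and was not tested.

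Mitosis RNA did not vanish in TGC: the 35 genes kept a median of 12.4% of their mTSC FPKM, from 5.69% for Ccnb2 to 45.3% for Cdc25c. Undifferentiated stem cells carried over at that share would have left as much Sox2, which kept 0.179% on average and 0.536% in the highest library, and Nr0b1 was listed at 0. A GC content or length trend that adds to the RNA left is argued against, as its removal did not deepen the median log2 change (-2.32, against -2.40 before). Cells that had lost the stem cell genes and still divided, or low expression in all giant cells, may account for it, and bulk values do not separate these.

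In the 10 splits of the 6 libraries into 3 and 3, the real split gave 8820 genes in limma (9108 at an unadjusted p under 0.05) and the highest of the others 0 (38 to 50 at an unadjusted p under 0.05). Each of the other splits put both cell types on both sides, so the difference between them entered the spread. Their 0 genes follow largely from that and do not measure what chance would give. For lists the real split gave 20 and the others 9 to 15, so camera with the preset correlation called lists where limma called 0 genes. As 3 libraries of a cell type cannot be divided evenly, part of the difference between cell types stayed in each of these comparisons. The 9 to 15 lists therefore do not measure false calls. With 10 splits the share that reach the real value, 1 of 10 in both cases, cannot be under 0.1, which is too few for a test at 0.05.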
